A study of Caenorhabditis elegans with 2 samples.

How the data were processed

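The samples are 2 biological replicates of 1 group: whole L1 hermaphrodites of a strain with a fosmid-based transgene that expresses SNU-23 with a C-terminal GFP and FLAG tag and carries unc-119(+) as a marker. Per the labels, chromatin was fragmented by sonication and precipitated with an antibody against GFP. The deposited files are peak lists on the builds ce10 and ce11: for each build, 30000 peak candidates per replicate, 30000 candidates from both replicates pooled, and a final list of peaks thresholded by the irreproducible discovery rate (IDR), a measure of rank agreement between replicates. Per the deposited file descriptions, candidates were called on each alignment together with a control alignment, and they include background peaks as input to IDR. The peak caller, the aligner and the version of IDR are not given in the sources used here. Control reads, alignments and signal tracks were not analysed here.

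For each peak the authors' lists give a signal value relative to the control, a −log10 q-value and the position of the summit. The signal is the authors' own value per peak, and it was used only to rank and describe peaks within a list and to compare matched peaks of the replicates. Its scale differs between lists: the median was 11.5 and 12.8 in the candidates of replicates 1 and 2 and 21.0 in the pooled candidates on ce11. The deposited −log10 q-value reached a ceiling of 4.38 in the pooled ce11 list, and all 6675 final ce11 peaks had it, so it could not rank them. In the candidates of replicates 1 and 2, 12543 and 11939 peaks were at the ceiling. The most frequent width, 396 bp, was shared by 81.2% of pooled candidates, so the candidate widths are mostly a default of the caller. Peaks of the pooled list were ranked by signal, ties by file order. Of 6675 final peaks, 5879 (88.1%) overlapped 1 of the strongest 6675 peaks of each replicate. No column of per-sample values was left unused.

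No file gives read numbers, so depth is unknown and no value carries an error from counting reads. Because the final list was made from both replicates together, replicate error is given by repeating each measurement on the strongest 6675 peaks of each replicate alone. Exact binomial (Clopper-Pearson) 95% intervals of shares cover counting error only, and they treat neighbouring genes as independent, although a peak between divergent genes marks both. The p-values of tests across genes or peaks describe these lists and do not measure variation between worm cultures.

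Annotation and sequence came from the Ensembl and RefSeq releases of the assembly WBcel235, whose chromosome lengths match ce11. Only ce11 lists were annotated, and no coordinates were converted or compared between builds. All 6 chromosomes were used and the mitochondrial genome was left out. Positions are 1-based. The 46890 annotated genes include 19973 coding genes. A gene counted as marked when a summit of the final list lay within 500 bp of its annotated 5' end. Each summit was also put in 1 class, in the order 5' end (within 500 bp), 3' end (within 500 bp), exon, intron, intergenic. Both were compared with 1000 circular shifts, in which all peaks of a chromosome move by the same random distance (two-sided permutation p, at least 0.002). Gene classes with at least 10 genes and 29 gene lists were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment and a threshold of 0.05. Coding lists were set against all other coding genes, RNA gene lists against all other genes. The lists were defined by gene symbol or class alone, so a few members do not share the function of the list's name. Expression levels were not used here.

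Introns were counted in the longest coding transcript of each gene. GC content and 6-base words were read within 50 bp of each summit and in windows centred 500 bp to either side. In the test of GC content, the sign of each peak's difference was permuted. The design, the gene lists and all alternatives not named below as added were fixed before the data were examined. The named genes are those of the 25 strongest final peaks found in both replicates, the 3 members with the highest signal in each list past the threshold, and snu-23 and unc-119. A result that this rule selects is not reported here. Other named genes were chosen after their values were seen. A gene named for a peak is the one with the nearest 5' end within 500 bp, or the one that contains the summit.

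Alternatives were each replicate alone, the stronger 3337 final peaks, windows of 250 and 1000 bp, peaks anywhere from 500 bp upstream to the 3' end, genes with a candidate peak as background, and circular shifts in place of Fisher's exact test. Further ones were gene length strata, other overlap rules and shorter sequence windows. Added after seeing the data were the classes as shares of summits not at 5' ends, coding 5' ends only, the nearest 5' end only, as many peaks as on ce10, a rotation of the marks along the order of genes, and other rank limits for X peaks.

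The gene list test was run on simulated data: peaks shifted at random, with summits added at known 5' ends so that 6 of 19 lists had 50% of their genes planted against a base of 12%. In 50 simulations it called 300 of 300 planted lists and 0 of 650 unplanted ones. The simulated lists were random sets of coding genes. Families clustered along a chromosome, lists below the base and RNA gene lists were not simulated. Nor were excesses smaller than the planted one, or the shortest lists, such as that of V-ATPase genes. Error rates for all of these are unknown. The position test called 2 of 50 simulated lists without any link to genes. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with a fixed random seed.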

Results

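The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from whole first-stage (L1) larvae of the nematode Caenorhabditis elegans. The hermaphrodite strain carried a transgene for SNU-23, the worm homolog of a protein of the spliceosome's tri-snRNP, fused at its C terminus to green fluorescent protein (GFP) and a FLAG tag. Larvae were collected 6 hours after synchronisation as starved L1 animals, and the tagged protein was precipitated with an antibody against GFP. The series holds 1 group of 2 biological replicates and no second group, so no difference between conditions can be measured. The comparisons made here set the peaks of this group against positions shifted along the chromosomes, against other genes and against each other. The lists give no read numbers, so the depth of each replicate is unknown. Positions are on ce11, and a gene is called marked when a peak summit of the authors' final list lies within 500 bp of its annotated 5' end.

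The same promoters and intergenic sites topped the lists of both replicates. The highest peak in either replicate lay upstream of rpl-3, which encodes a protein of the large ribosomal subunit, with a signal of 1310.1 in replicate 1 and 1505 in replicate 2. The next highest in both lay upstream of tasp-1, at 1149 and 1351. All 25 of the strongest pooled peaks ranked among the first 100 of each replicate. Of the 6675 strongest peaks of replicate 1, 5826 (87.3%, exact 95% interval 86.5 to 88.1%) had their summit inside 1 of the 6675 strongest peaks of replicate 2, and the reverse share was 87.3%. Circular shifts of 1 list along its chromosomes gave 2.08% on average and at most 2.76% in 1000 shifts (one-sided permutation p = 0.001, the smallest they can give). Across 6637 final peaks with a value in both replicates, log10 signals had a Pearson r of 0.936 and a Spearman rho of 0.918 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). These are correlations across peaks, which are not independent replicates. The signal of replicate 2 was a median 1.15 times that of replicate 1, and the log2 ratio had a standard deviation of 0.36 over peaks. The final list, thresholded by IDR, was exactly the top 6675 pooled candidates by signal. Its peaks were therefore selected for high pooled signal, not each for its own agreement. Over the 22626 pooled candidates matched in both replicates, rho was 0.875 and that standard deviation 0.66. Of all 30000 candidates of replicate 1, 64.4% had their summit inside a candidate of replicate 2.

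**Figure D1:**
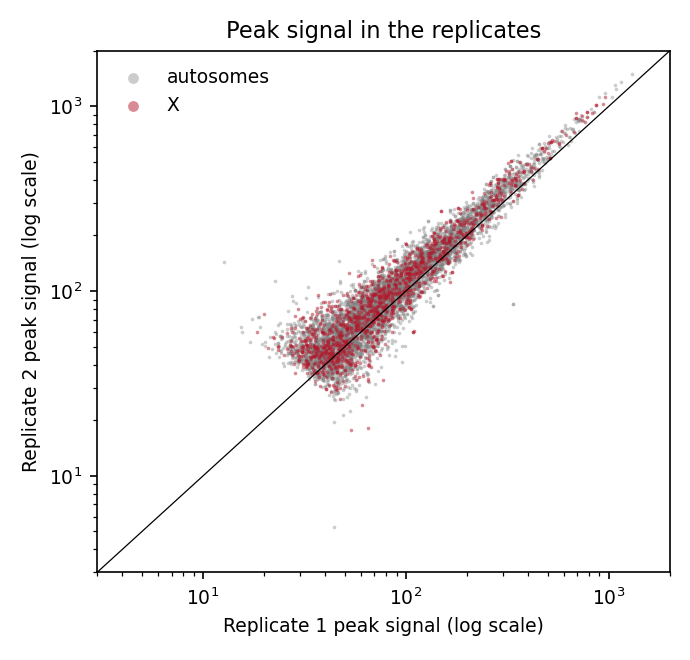
Peak signal of replicate 2 (vertical, log scale) against replicate 1 (horizontal, log scale), with 1 point for each final ce11 peak that has a value in both, red on chromosome X and grey on the autosomes, and a line of equal signal. The 6637 peaks follow the line with a Spearman rho of 0.918, and the highest points lie slightly above it.

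Peaks of tagged SNU-23 clustered around annotated 5' ends, those of non-coding RNA genes included, and were rare in exons away from gene ends. Of 6675 summits, 3953 (59.2%, exact 95% interval 58.0 to 60.4%) were within 500 bp of an annotated 5' end, 2.02 times the mean of 29.3% from 1000 circular shifts. The strongest 1000 peaks reached 74%, among them those at rpl-3, cdc-48.1 and cox-5A. Coding 5' ends alone had 2805 summits within 500 bp, 2.28 times the shifts (two-sided permutation p = 0.002 for both 5' end shares, the smallest they can give). Over 1000 bp from any coding 5' end lay 46.3% of summits. The other classes were compared among the 2722 summits not at 5' ends, since a rise at 5' ends lowers every other share of the total. Exons held 98 of these against a mean of 22.7% under shifts, and regions within 500 bp of a 3' end 14.8% against 17.3% (permutation p = 0.002 for each). Intergenic sequence held 46.5% against 24.6% (permutation p = 0.002), and introns 35.1% against 35.4%, no detectable difference (permutation p = 0.799). In the stronger part of the list introns held 32.3% against 35.5% (permutation p = 0.006) and intergenic sequence 51.1%. The single replicates gave 59.7% and 59.4% at 5' ends, a spread far below the distance from the shifts. The size of the excess depended on the window and the list. It was 2.77 times the shifts within 250 bp and 1.45 times within 1000 bp. Over all 30000 pooled candidates the share within 500 bp was 36.7%, 1.25 times the shifts.

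Around protein-coding genes the summits stood on the upstream side. Within 500 bp of a coding 5' end there were 2805 summits, of which 2465 (87.9%, exact 95% interval 86.6 to 89.1%) were upstream, at a median of -150 bp with quartiles of -254 and -59 bp. The medians of the single replicates were -152 and -150 bp. At rpl-3 the summit was at -282 bp, at cdc-48.1, which encodes a AAA ATPase, at -167 bp, and at iff-2, which encodes translation factor eIF5A, at -75 bp. Annotated 5' ends of worm genes are often trans-splice sites, so the distance to the transcription start is not given by these values. In the pooled list of 30000 peak candidates, the lowest-ranked 6675 had 24.9% of summits at 5' ends, and the odds were 4.38 times higher in the final list by Fisher's exact test. That reference share lay below the mean of 29.3% from circular shifts of all 30000 candidates, so this ratio is not one against random positions.

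**Figure D2:**
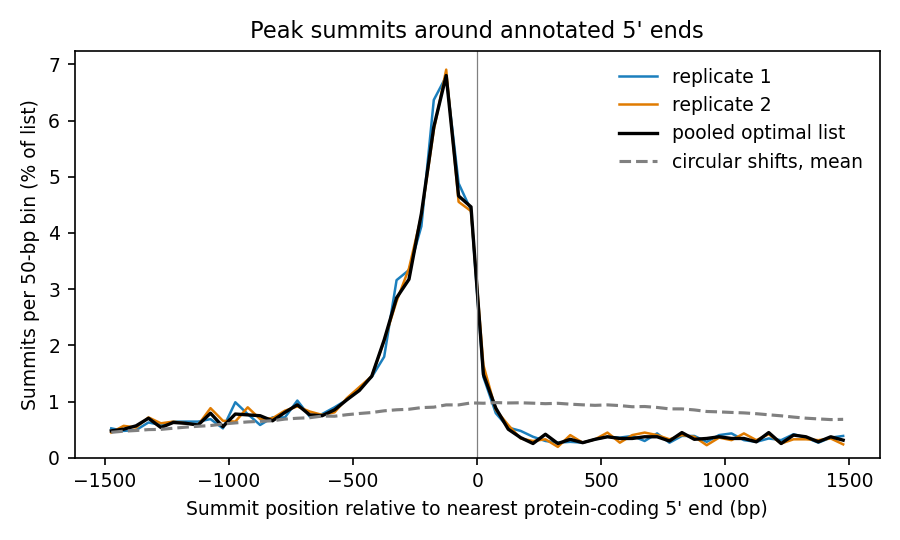
Share of summits per 50 bp bin (vertical, % of each list) by distance from the nearest protein-coding 5' end (horizontal, bp, negative upstream) for the pooled final list, each replicate's strongest 6675 peaks and the mean of 200 circular shifts. The highest bin, from -150 to -100 bp, holds 6.80% of pooled summits, 6.79% in replicate 1 and 6.91% in replicate 2, against 0.942% under shifts.

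Among the classes of genes, those for transfer RNAs were marked most often and those for 21U-RNAs (piRNAs) and pseudogenes seldom. A summit lay at 333 of 612 tRNA genes (54.4%, exact 95% interval 50.4 to 58.4%), against 11.8% of all other genes (adjusted exact p = 3.3e-140 by Fisher's exact test). Small nucleolar RNA genes, which guide RNA modification, were marked at 125 of 346 (36.1%, adjusted exact p = 5.1e-30), and spliceosomal and spliced leader snRNA genes at 33 of 129 (25.6%, adjusted exact p = 5.8e-05). Protein-coding genes were marked at 3355 of 19973 (16.8%, adjusted exact p = 7.9e-141), unclassified non-coding RNA genes at 1409 of 7764 (18.1%, adjusted exact p = 6.0e-60), microRNA genes at 49 of 261 (18.8%) and long intergenic RNA genes at 34 of 194 (17.5%). The microRNA call (adjusted exact p = 0.0033) did not hold with a 250 bp window or when only the nearest 5' end counted (odds ratio 1.13). The long intergenic RNA call (adjusted exact p = 0.0446) was lost with either replicate alone, in the stronger peaks and with a 250 bp window. Only 385 of 15363 piRNA genes (2.51%) and 40 of 2128 pseudogenes (1.88%) had a summit, fewer than the 5.51% and 5.81% of circular shifts. The adjusted exact p was 1.3e-72 for pseudogenes and, for piRNA genes, below the smallest number the software holds. These tests treat genes as independent, although neighbouring genes can share a peak. Circular shifts, which keep the spacing of peaks, gave a two-sided permutation p of 0.002 for each, the smallest they can give. The antisense RNA genes (8 of 100) and the rRNA genes (0 of 20, upper limit 16.8%) did not pass the threshold. Altogether 7 of the 11 classes were above the other genes and 2 below.

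The snRNA class split sharply between spliced leader families. SL2 RNA genes, which supply the leader added to downstream genes of operons, had a summit at 14 of 18 (77.8%, exact 95% interval 52.4 to 93.6%). The strongest were sls-2.4 on chromosome I (gene at 4172206 to 4172315, signal 2123, rank 6), sls-2.1 on chromosome II (5844865 to 5844974, signal 1763, rank 13) and sls-2.2 on chromosome II (5543598 to 5543707, signal 1554, rank 28). The summits were 40, 58 and 41 bp upstream, at -40, -58 and -41 bp. None of the 12 SL1 RNA genes had a final peak (0%, upper limit 26.5%), no detectable difference from other genes (unadjusted exact p = 0.383). Of these SL1 genes, 0 had even a candidate peak, as was true of the 20 rRNA genes. SL1, rRNA, histone and major sperm protein genes occur as near-identical copies, so a missing peak there is uncertain. Other snRNA genes were marked at 19 of 99 (19.2%, unadjusted exact p = 0.0453). The division into these parts was made after the values were seen. The strongest peaks within 500 bp of the 5' end of a tRNA gene lay on X. The first, for WBGene00022939 (8036685 to 8036757, signal 1707), had its summit 318 bp downstream of the 5' end, beyond the gene's 3' end. It was shared with C18A11.13, whose 5' end is nearer. The next were at WBGene00023117 (410391 to 410462, signal 899) and WBGene00023110 (3036164 to 3036235, signal 878). The strongest snoRNA gene peaks were at F54E7.10 on III (signal 1524, shared with rps-12, whose 5' end is nearer), Y53F4B.47 on II (1369) and W06H8.17 on V (1241).

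Genes for protein synthesis, splicing, protein turnover and respiration were marked several times more often than other protein-coding genes, and chemoreceptor genes far less often. Of 29 lists, 17 were higher, 6 lower and 6 not past the threshold (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 29 lists). Ribosomal protein genes had the highest share, 69 of 83 (83.1%, exact 95% interval 73.3 to 90.5%, adjusted exact p = 3.1e-39) against 16.5% of the others, an odds ratio of 24.9. That ratio depended on the window: it was 2.02 within 250 bp (adjusted exact p = 0.0215) and 4.36 when only the nearest 5' end counted, against 8.35 and 7.75 for proteasome genes. Among them rpl-3 had a pooled signal of 2804, rpl-15 2300 and rpl-20 2162. The peak at rpl-20 was shared with the divergent gene Y17G9B.5. Translation factors followed with 31 of 42 (73.8%, adjusted exact p = 2.2e-15), including iff-2 (1659), eef-1A.1 (1253) and eef-1G (963), the last 2 for subunits of elongation factor 1. Of the aminoacyl-tRNA synthetases, which charge tRNAs, 13 of 31 were marked (41.9%, adjusted exact p = 0.0013), led by ears-2 (594), nars-1 (565) and mars-1 (377). This call was lost in the stronger peaks (odds ratio 2.42, adjusted exact p = 0.057).

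Genes for the machinery SNU-23 is named after were themselves among the marked. Spliceosome protein genes had a summit at 53 of 79 (67.1%, exact 95% interval 55.6 to 77.3%, odds ratio 10.2, adjusted exact p = 1.5e-22), and the single replicates each gave 53. The ratio was 5.67 within 250 bp and 4.99 when only the nearest 5' end counted. Among the 53 marked genes is snu-23 itself (rank 4394), which the transgene also carries. The strongest were mog-4, a DEAH-box helicase gene (897), snr-4, an Sm protein gene (765), and prp-40 (661). RNA polymerase and general transcription genes were marked at 29 of 69 (exact 95% interval 30.2 to 54.5%, adjusted exact p = 1.5e-06), with rpb-11 (791), cdk-7 (750.2) and taf-4 (673) at the top. Cell cycle and replication genes were marked at 26 of 51 (exact 95% interval 36.6 to 65.2%, adjusted exact p = 5.0e-08). Their leader cdc-48.1 (2356) acts in protein extraction and turnover, while lin-35 (871) and efl-1 (794) encode the Rb and E2F homologs. Histone genes were marked at 22 of 81 (27.2%, adjusted exact p = 0.0211), including his-37 (1274), the H2A.Z gene htz-1 (887) and his-67 (656). The histone call was lost with a 1000 bp window (adjusted exact p = 0.0901), over the whole gene (adjusted exact p = 0.184) and when each summit counted only for its nearest 5' end (adjusted exact p = 0.366).

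Proteasome genes were marked at 25 of 33 (75.8%, adjusted exact p = 4.6e-13), with rpn-3 (1379), rpt-2 (595) and pas-4 (514) leading. The rpn-3 peak was shared with hsp-110 on the opposite strand. Heat shock protein and chaperonin genes reached 32 of 61 (52.5%, adjusted exact p = 5.5e-10), including dnj-13 (1535) and the Hsp70 gene hsp-1 (1509). This call also ended when only the nearest 5' end counted (odds ratio 1.97, adjusted exact p = 0.063). Oxidative phosphorylation genes stood at 33 of 53 (62.3%, adjusted exact p = 4.6e-13), led by the cytochrome c oxidase genes cox-5A (1788) and cox-5B (1012) and the ATP synthase gene atp-1 (890.2). V-ATPase genes, for the proton pump of acidic organelles, stood at 11 of 20 (55%, adjusted exact p = 2.0e-04), led by vha-8 (919.9), vha-12 (645) and vha-1 (602). The V-ATPase call was lost within 250 bp (odds ratio 1.95, adjusted exact p = 0.332) and among genes with a candidate peak (1.78, adjusted exact p = 0.46). Muscle structure genes were marked at 24 of 44 (54.5%, adjusted exact p = 3.4e-08), with lower signals: the actin gene act-2 (541), the kindlin gene unc-112 (360), and the cofilin gene unc-60 (321).

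Of the RNA gene lists, tRNA (adjusted exact p = 1.3e-139), snoRNA (1.6e-29), SL RNA (14 of 30, 7.8e-06), snRNA (7.1e-05) and microRNA genes (0.0035) were higher. The microRNA peaks with the highest signal were shared: cel-mir-5549 with eef-1A.1, and cel-mir-54 with cel-mir-55 (941). Chemoreceptor genes were at 14 of 1365 (1.03%, exact 95% interval 0.562 to 1.71%, adjusted exact p = 3.4e-89). The highest signal among these 14 was at sri-5 (614). Not all of the 14 are receptor genes: srrt-1, for example, encodes a Serrate homolog and srp-7 a serpin. Major sperm protein genes were marked at 0 of 31 (upper limit 11.2%, adjusted exact p = 0.0083), a call lost within 250 bp (adjusted exact p = 0.06), in the stronger peaks (0.0913) and among genes with a candidate peak (0.619). Also lower were intestinal genes at 2 of 70 (2.86%, adjusted exact p = 9.3e-04), namely erm-1 (227) and fat-6 (125), and homeobox and bHLH factor genes at 7 of 106 (exact 95% interval 2.70 to 13.1%, adjusted exact p = 0.0052), led by hlh-11 (rank 108) and ceh-38 (rank 126, signal 899). Neuronal genes were marked at 16 of 199 (8.04%, adjusted exact p = 9.2e-04), among them unc-76 (466), ric-19 (388) and unc-40 (357), a call lost when only the nearest 5' end counted (odds ratio 0.588, adjusted exact p = 0.0643). Cuticle collagens (20 of 175), germ line genes (11 of 64), nuclear hormone receptors (54 of 269), vitellogenins (0 of 6, upper limit 45.9%), rRNA genes (0 of 20) and heterochronic regulators (2 of 11) did not pass the threshold. Cuticle collagens were close to it (odds ratio 0.637, adjusted exact p = 0.0805) and were called lower with each replicate alone (0.559 and 0.589). Against shifted peaks rather than other genes, only chemoreceptors and piRNA genes remained lower, cuticle collagens were called higher (1.83 times the shifts, adjusted permutation p = 0.0263), and neuronal genes were 1.23 times the shifts (adjusted permutation p = 0.535). Among genes that have any candidate peak, 11 lists were higher. The calls lost there include those of RNA polymerase and transcription genes (odds ratio 1.76, adjusted exact p = 0.106), cell cycle genes (2.10, 0.058), heat shock genes (1.83, 0.0726) and synthetases (1.57, 0.506).

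**Figure D3:**
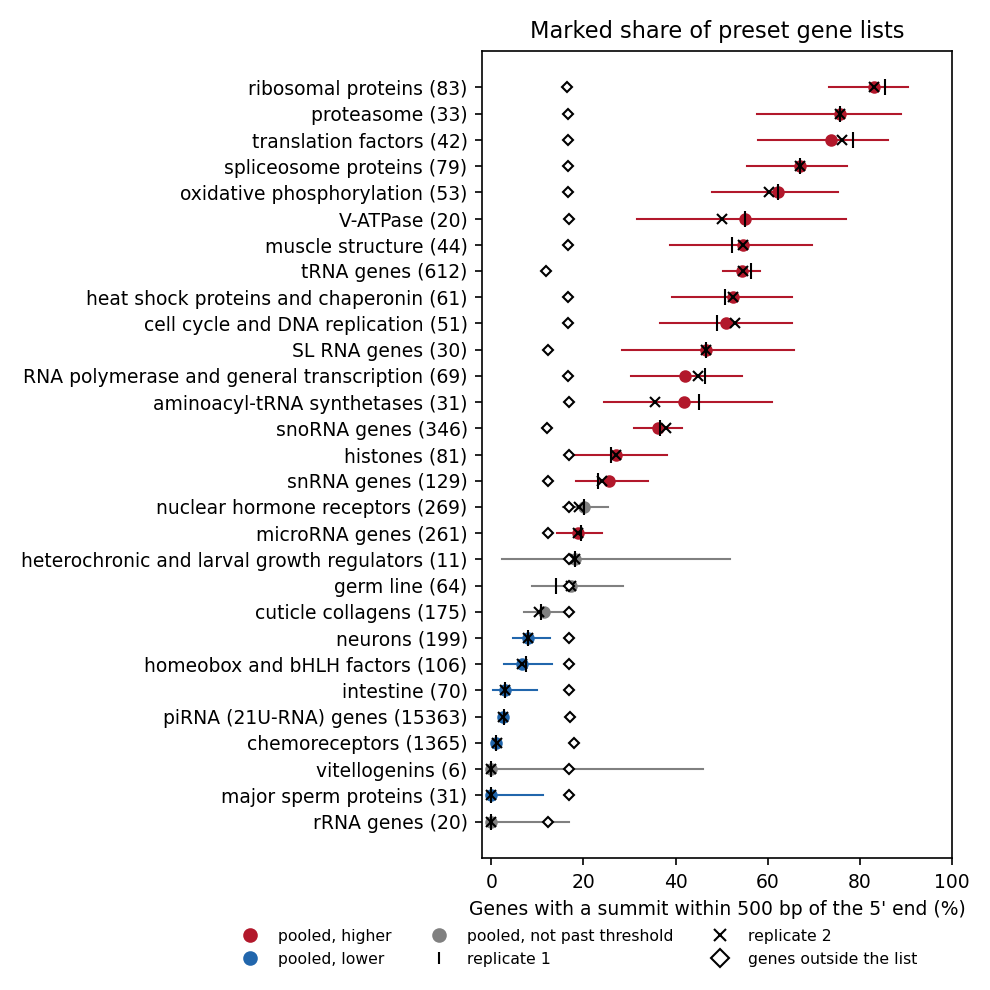
Share of genes with a summit within 500 bp of the 5' end (horizontal, %) for 29 gene lists with their sizes, as circles for the pooled list with exact 95% intervals (counting error), bars for replicate 1, crosses for replicate 2 and open diamonds for genes outside the list. Red lists are higher and blue lists lower than the other genes, from 83.1% for ribosomal proteins to 0% for major sperm proteins.

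Intron-containing genes were marked more often than intronless genes, but intronless genes were marked too. A summit lay at 3272 of 19280 protein-coding genes with an intron and at 83 of 693 without (exact 95% interval 9.65 to 14.6%), an odds ratio of 1.502 (95% interval 1.19 to 1.90, Fisher's exact p = 4.2e-04). Intronless genes exceeded the 6.13% of circular shifts, whose highest value was 8.95% (permutation p = 0.002, the smallest they can give). The share was 13.3% in genes with 1 to 2 introns, 17.7% with 3 to 5, 18.8% with 6 to 10 and 18.4% with over 10. When each summit counted only for its nearest 5' end, 42 of 693 intronless genes (6.06%) remained marked. Of the genes with an intron 12.3% did, an odds ratio of 2.18 (95% interval 1.59 to 2.99). Those nearest-end shares were not compared with circular shifts. Among the 6599 coding genes with a candidate peak at the 5' end, 3272 of 6419 with and 83 of 180 without introns were in the final list, a difference that was not detectable (odds ratio 1.22, 95% interval 0.903 to 1.64, exact p = 0.2). Intronless genes are short, with a median of 312 bp, and stratified by gene length the odds ratio was 1.33 (95% interval 1.04 to 1.70). Expression was not analysed here.

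**Figure D4:**
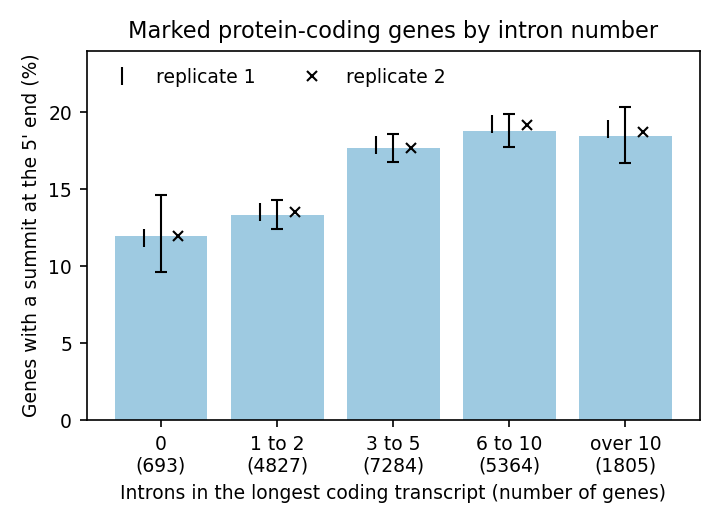
Share of protein-coding genes with a summit at the 5' end (vertical, %) by number of introns in the longest coding transcript (horizontal, with gene numbers), as bars for the pooled list with exact 95% intervals (counting error), ticks for replicate 1 and crosses for replicate 2. The share is 13.3% with 1 to 2 introns and 18.8% with 6 to 10, and lower without introns.

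Genes on the X chromosome were marked about as often as autosomal genes, yet X held many of the strongest peaks that lie far from genes' 5' ends. A summit lay at 448 of 2731 X-linked coding genes (16.4%) and 2907 of 17242 autosomal ones (16.9%), an odds ratio of 0.968 (95% interval 0.868 to 1.08, Fisher's exact p = 0.563). The ratio fell to 0.821 in the stronger part of the list (exact p = 0.0047) and to 0.849 with a 250 bp window (exact p = 0.0163). Chromosome III had the highest marked share, 24.2%, and chromosome V, rich in chemoreceptor genes, the lowest, 11.8%. X carried 1353 peaks, 20.3% of all on 17.7% of the sequence.

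Among the 200 strongest peaks, 21 of 41 on X (51.2%) but 36 of 159 on autosomes (22.6%) were away from 5' ends. The odds ratio was 3.59 (Fisher's exact p = 7.6e-04). In replicate 1 alone the numbers were 20 of 40 and 32 of 160 (exact p = 2.4e-04), and in replicate 2 alone 22 of 44 and 35 of 156 (exact p = 6.1e-04). This limit of 200 peaks was chosen after the peaks were seen, and the odds ratio depended on it: 6.29 in the strongest 100, 2.04 in 500, 1.94 in 1000 and 1.22 over all 6675 peaks (44.6% on X against 39.8%). Of the 25 strongest peaks, 15 were at 5' ends and 10 were not, 9 of these on X. On X they lay in intergenic sequence at 13700493 to 13701234 (signal 2078), 4208533 to 4209637 (1957), 9465475 to 9466220 (1877), 11093784 to 11094581 (1874), 11937200 to 11937867 (1661), 16681844 to 16682390 (1616) and 14525369 to 14526451 (1594). A pair lay in introns, of mom-1, a Porcupine homolog gene in Wnt secretion, at 6296217 to 6296991 (1745), and of Y41G9A.17 at 2996383 to 2997494 (1561). The remaining one was intergenic on V at 20778052 to 20778804 (1633), 1981 bp from the 5' end of hif-1, which encodes the hypoxia-inducible factor. X peaks among the 200 had a median width of 605 bp and autosomal ones 442 bp. Others of the 25 marked the non-coding genes C18A11.13 (1707), W06B11.7 (1605; 291 bp from puf-9) and F56F3.11 (1579; 263 bp from rps-1), and the genes rpl-35 (2003), rpl-12 (1568) and tos-1 (1557).

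**Figure D5:**
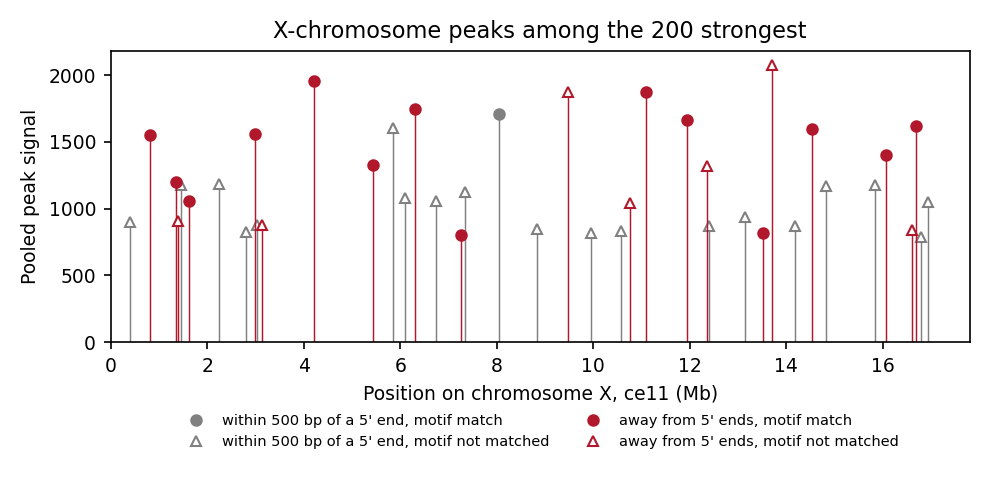
Pooled signal (vertical) and position on chromosome X (horizontal, ce11, Mb) of the 41 X peaks among the 200 strongest, red away from 5' ends and grey within 500 bp of one. Circles have a match with at most 2 mismatches to the 12 bp X recruitment motif described in the closing section within 200 bp of the summit, and triangles have none; 14 of the 21 red peaks are circles.

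Both genes carried by the transgene had peaks of moderate rank. At snu-23 (III, 7769163 to 7770120, minus strand) a peak with its summit at -71 bp ranked 4394 (signal 55.4 in replicate 1 and 62.1 in replicate 2), and another at -1080 bp ranked 1742 (270.0). At unc-119 (III, 10902641 to 10908935), the selection marker, summits lay inside the gene at 770 and 2660 bp from its 5' end and ranked 3852 (137) and 3951 (133). Of these 4 peaks, the 1 at -1080 bp from snu-23 was above the median signal of the final list, 158. Endogenous and transgenic copies cannot be separated in these lists.

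Summits were richer in G and C than their surroundings and carried GAGA and CG-containing words. In 6675 peaks, GC content within 50 bp of the summit was 45.5% ± 7.37 (SD over peaks) and 35.3% ± 6.53 in windows 500 bp away, a difference of 10.2 percentage points (SE 0.116), with the summit higher in 85.6% of peaks (permutation p = 1e-04, the smallest that 10000 resamples can give). The word GAGAGA or its complement was present in 31.1% of odd-ranked and 28.8% of even-ranked summits, against 5.48% and 5.00% of flanks. The word ACGCGC was present in 9.62% and 9.71% against 1.29% and 1.29%, and ACGCAG in 16.9% and 15.2% against 1.92% and 2.23%. Peak widths in the final list had a median of 287 bp (99 to 2594 bp), and neighbouring summits were a median 6464 bp apart.

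The final list was longer on the older build ce10, with 8993 peaks, than on ce11, with 6675. Their median signals were 116 and 158, and the lowest signals 45.8 and 71.7. The highest signal, at rpl-3 on ce11, was 2804, and the highest on ce10 was 2803. Each final list was exactly the top of its own 30000 pooled candidates by signal. Counting repeated intervals once left 8831 and 6552 peaks.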

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

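Both tests in this part were chosen after the result was seen. Peaks that the final ce11 list leaves out still favoured gene starts. Pooled ce11 candidates ranked 6676 to 8993, beyond the final ce11 list but within the number of peaks kept on ce10, had 41.8% of their 2318 summits at 5' ends (exact 95% interval 39.7 to 43.8%). The lowest-ranked candidates had 24.9%, an odds ratio of 2.16 (Fisher's exact p = 3.7e-51). Their share lay below the mean of 29.3% from circular shifts of all 30000 candidates, so this ratio overstates the excess over random positions. Candidates ranked 8994 to 11911 had 37.1%. What drew attention is a signal in peaks that no other comparison here uses as its main list.

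The pattern behind it is that the final list has fewer peaks on ce11 than on ce10. The values argue against different reads or alignments behind the lists: 99.3% of ce10 pooled candidates had a ce11 partner on the same chromosome with equal width and summit offset, signal within 1% and a matching neighbour, against 25.2% when chromosomes were mismatched. A different threshold along nearly the same ranking may account for it, since 99.1% of final ce11 peaks had such a partner in the final ce10 list (1.92% with mismatched chromosomes), with a median rank difference of 0. A first form of this test without the neighbour was dropped because mismatched chromosomes also gave partners for most peaks. Why the thresholds differ stays open, and no biological explanation was tested, since both builds hold the same 2 replicates.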

How the results depend on the processing

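Among results that answer a comparison, 90 alternative values kept their direction and side of the threshold, or stayed within 1.5 times as counts. The 5' end share in other peak sets entered this tally under 2 headings. The replicate correlation over all candidates was entered as kept without a test. The tally is therefore not a number of independent checks. Of the others, 2 lost their call, 2 gained one, 2 counts moved further and 4 turned direction. In the stronger 3337 peaks the intergenic share was 16.2%, below instead of above the mean of the shifts but within their range, and as shares of summits not at 5' ends introns held 35.1%, not past the threshold; the classes are exclusive, so a rise at 5' ends lowers the rest. The X to autosome odds ratio, not past the threshold in the full list, was 0.821 in those peaks and 0.849 with a 250 bp window, both past it, and 1.01 with 1000 bp, 1.00 with the ce10 number of peaks and 1.04 with the nearest 5' end only, none past it. With genes that have a candidate peak as background, 11 lists were higher and the intron odds ratio was 1.22, not past the threshold; fewer genes enter that test. Circular shifts left 2 lists lower, since they compare with random positions and not with other genes; cuticle collagens were at 1.83 times the shifts, called higher, and neuronal genes at 1.23 times, not past the threshold. Against other genes, collagens instead gained a lower call without replicate 1 (0.559) or 2 (0.589), with 1000 bp (0.609), over the whole gene (0.514) and with the ce10 number (0.614).

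For single lists and classes, 337 values kept their call and direction, 26 lost the call, 11 gained one and 19 turned. RNA gene groups that are both a class and a list, such as tRNA genes, entered as each, so these values partly repeat. MicroRNA genes had an odds ratio of 0.926 with a 250 bp window, as class and list, and as list 0.872 with the candidate background. Their call was also lost with the nearest 5' end (1.13), and as list over the whole gene (1.34) and under rotation (1.19). Apart from microRNA and neuronal genes, the turns were of groups not past the threshold in the full list. Germ line genes had 0.552 in the stronger peaks, 0.845 with the ce10 number, 0.761 with 1000 bp, 0.749 with the nearest 5' end, 0.986 under rotation and 0.794 to 1.02 without replicate 2 or 1, but 3.55 with the candidate background, not past the threshold, and 2.71 times the shifts, past it. Heterochronic genes had 0.828 in the stronger peaks, 0.905 with the ce10 number, 0.781 with 250 bp, 0 with the nearest 5' end and 0.967 with the candidate background, but 2.10 with 1000 bp and 6.63 over the whole gene, where the call was gained. Nuclear hormone receptors had 0.772 in the stronger peaks and 0.883 with that background, but gained a higher call with the ce10 number (1.36), the nearest 5' end (1.54), rotation (1.45) and shifts (3.71 times), and antisense RNA genes 1.19 with 1000 bp. For SL RNA genes with that background all 14 were marked, so no finite odds ratio exists. Apart from the reasons given, the cause was not tested. Without replicate 1 or 2, the 5' end share ranged from 59.4 to 59.7% and the intron odds ratio from 1.52 to 1.56. Shares of summits not at 5' ends, the nearest 5' end, coding 5' ends, the ce10 number, rotation and the rank limits for X were chosen after seeing the data. No paired analysis was possible because there is only 1 group. Depth is unknown, so what it limits cannot be given.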

Other observations

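Families of gene symbols, examined after the other results were seen and partly contained in the lists above, showed further groups. Of 117 families with at least 15 coding genes, 18 were marked more and 29 less often than other coding genes (Fisher's exact test, adjusted over families). Families were not compared with circular shifts, which marked 6.25% of coding genes on average. A family called lower here is therefore below other coding genes and not necessarily below random positions. Nuclear pore genes (npp) had a summit at 20 of 26 (76.9%, adjusted exact p = 4.8e-10), and mitochondrial ribosomal protein genes at 17 of 29 (mrps, adjusted exact p = 5.1e-06) and 19 of 41 (mrpl, adjusted exact p = 8.5e-05). Vesicle sorting genes (vps) were marked at 17 of 31 (adjusted exact p = 1.7e-05), and cyclophilin genes (cyn) at 10 of 16 (adjusted exact p = 2.9e-04). C-type lectin genes (clec) were marked at 4 of 240 (adjusted exact p = 6.5e-13) and insulin-like peptide genes (ins) at 0 of 38 (adjusted exact p = 0.0057). F-box genes of the fbxa family were marked at 10 of 170 (5.88%, adjusted exact p = 2.0e-04), near the share of coding genes under shifts.

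Of the tests that follow, those of introns, of accessible DNA and of neighbours of snoRNA genes were written after the values were seen, as was the choice of the 200 strongest peaks. Strong X peaks away from 5' ends may be sites that recruit the dosage compensation complex, which lowers X expression in hermaphrodites. A 12 bp motif known from such sites, TCGCGCAGGGAG, was matched with at most 2 mismatches within 200 bp of the summit in 14 of 21 of these peaks (66.7%, exact 95% interval 43.0 to 85.4%), against 0 of 36 autosomal peaks of the same ranks (upper limit 9.74%; Fisher's exact p = 1.5e-08) and 1 of 20 X peaks at 5' ends. Stratified by GC content, the odds ratio of a rank in the first 200 for X was 2.31 (95% interval 1.34 to 3.98), and 2.17 without strata. The strata thus did not remove the excess on X. Whether base composition plays a lesser part stays open, since the interval from 21 peaks is wide. Unannotated starts of outrons, the leader RNA removed in trans-splicing, stay open too, since 21 peaks are too few to decide. Of these peaks 33.3% (14.6 to 57.0%) lay within 2000 bp upstream of a coding gene, as did 30.6% of the autosomal peaks. Over all final peaks away from 5' ends the motif was matched in 30 of 603 on X (4.98%) and 31 of 2119 on autosomes (1.46%), an odds ratio of 3.53 (Fisher's exact p = 2.6e-06). The 30 include the 14 above, so this comparison is not independent of the first. Peaks beyond the strongest 200 were not tested separately. The hypothesis rests on sequence alone, and no biological group in the design bears on it.

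Peaks at tRNA, snoRNA and SL2 RNA genes, of which tRNA genes have no spliceosomal introns, raise the question of what the tagged protein was recovered with. Spill-over from neighbouring coding genes was argued against for tRNA genes: of the 427 with no coding 5' end within 1000 bp, 229 were marked (53.6%, highest shift 11.2%), as were 66 of 211 such snoRNA genes (31.3%, highest shift 12.3%). Recruitment at introns of coding genes was argued against for tRNA genes too, since 83 of the 145 with no part of a coding gene within 1000 bp were marked (57.2%, exact 95% interval 48.8 to 65.4%, highest shift 15.9%). It stays open for snoRNA genes, with 15 of 51 such genes marked (29.4%, 17.5 to 43.8%, highest shift 19.6%), and for SL2 RNA genes, of which none lies so far from a coding gene. Recovery of accessible or strongly transcribed DNA whatever the tagged protein stays open: the 54.4% of tRNA genes marked cannot be told apart from what an untagged strain or another tagged protein could give, which was not analysed here.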
